A study of Homo sapiens with 4 samples.

How the data were processed

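Expression was measured with 1-colour Agilent microarrays (Cy3) in RNA from 4 cultures, H2052 and H2452 each untreated and with an antibody against S100A11 at 1 µg/ml for 24 h. Each of the 4 groups was 1 array, and the 4 arrays lay on 1 slide and were read in 1 scan. Each array held 62976 spots, of which 58717 were not controls, and these covered 50599 distinct probes.

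Per the file headers, the images were read with Agilent Feature Extraction 11.0.1.1, which gives for each spot a processed signal, an intensity after background subtraction in which low values are replaced by a positive surrogate. The values deposited by the authors in the series table are on a log2 scale, rounded to 1 decimal, with the same median, 4.1, in every array. They correlated with the log2 processed signal at r = 0.9998, 0.9998, 0.9993 and 0.9998 over the 4 arrays. Their distributions matched quantile normalization, and the tool behind them was not given in the sources used here.

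All values were computed from the spot intensity files with R 4.3.3 and limma 3.58.1, and figures with Python 3.11.15 and matplotlib 3.10.9. Spots that the scanner software marked as outliers were dropped, which left 19 probes without any spot on at least 1 array. The log2 processed signal was averaged over the spots of a probe, and each array was scaled by its 75th percentile. This percentile was taken over probes well above background on all 4 arrays. A rule fixed before the data were examined called for this where under 50% of the probes are well above background, and over distinct probes the shares were 47.8%, 48.9%, 46.9% and 47.5%. Over spots they were 51.6%, 52.6%, 50.7% and 51.3%, so the rule applies only when distinct probes are counted. The scaling was first computed over all non-control probes and was changed to that rule after results had been seen. The first version is kept as an alternative.

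Probes were named from their RefSeq accession, with gene names alone and no positions taken from the reference, which is on a later genome build than the array's annotation. This named 28174 probes for 20500 genes and left 22425 probes out, since no accession gave them a gene. Of the genes, 5764 had more than 1 probe, and each was represented by the probe with the highest mean level over the arrays. Genes were counted in a line where their probe was well above background on both arrays of the line. Limma used the 14159 genes well above background on at least 2 arrays, and the correlation and gene lists used the 13229 well above background on all 4.

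Within a line, antibody and untreated arrays were compared by a rule of size, at least 2-fold, with no test, since each group was 1 array. Where a probe was well above background on 1 array of the line, the fold was computed as a lower bound. Across lines, the counts shared were set beside the number that independent lists would share. The antibody effect and the line difference were tested in 1 limma fit with line and antibody as terms, empirical Bayes moderation and 1 residual degree of freedom, at a Benjamini-Hochberg adjusted p under 0.05. The fit was tested on simulated data of the same design, where it recovered 0 of 50 genes with a log2 change of 0.5 and 50 of 50 with a change of 3, with 3 false calls.

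The 33 gene lists, with 601 of their 610 entries on the array, were fixed before the data were examined. For each list and line, the median log2 fold change was placed as a percentile among 10000 random lists of the same size, drawn with seed 1 from genes in the same of 20 bins of mean expression. The percentile is a description, and a median is called outside where it is beyond the central 95%. Of 100 random lists drawn as a check, 96 fell inside.

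Genes were named by a rule fixed before the data were examined, which leaves out symbols of uncharacterised loci. It takes S100A11 always. Per line it takes the 10 genes with the largest increase and the 10 with the largest decrease among those well above background on both arrays, and up to 3 per direction with the largest lower bound. For both lines it takes the 12 per direction with the largest smaller-of-the-lines difference. It takes all genes past the limma threshold for the antibody if 20 or fewer, and the 10 per direction with the largest line difference among those called. Per gene list it takes up to 4 members with the largest mean difference and every member at least 2-fold different in a line. The text gives a selection of these list members, and leaves out some other genes that the rule gives.

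Bright patches were found after the data were seen. A spot counted as in a patch where at least 5 of its 18 neighbours were more than 1 log2 unit above the second-lowest array at the same spot. Such spots were left out on all 4 arrays as 1 alternative, and a stricter version asked for 4 of 18. On simulated patches the rule found 96.9% of 3112 spots and marked 1.34% of the spots outside them. Genes measurable fell from 20500 to 18436 with patch spots left out. The naming rule was applied again to these values.

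The alternatives fixed before the data were examined were normexp background correction, quantile normalization, median centring, cyclic loess, scaling on spike-in control probes, the authors' values, the mean over the probes of a gene, a filter for all 4 arrays and no filter. For counts, thresholds of 1.5-fold and 3-fold were tried, and for limma an intensity trend, a robust prior, no replicate block and each line on its own. Normexp used the median foreground and background signals with an offset of 50, since the files hold no mean foreground signal. The added alternatives, chosen after seeing the data, were both patch rules and the percentile over all probes. Spot noise was the SD between repeated spots of 1 probe on 1 array, with medians of 0.071, 0.052, 0.057 and 0.061 on the log2 scale. The number of arrays limits the precision of every value.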

Results

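Gene expression was measured in H2052 and H2452, established cell lines of malignant pleural mesothelioma, a cancer of the membrane that lines the lung and the chest wall. Each line was cultured for 24 h without treatment or with an antibody against S100A11 at 1 µg/ml. No group had a control antibody, so binding of S100A11 and other effects of adding an antibody cannot be told apart. S100A11 is a calcium-binding protein of the S100 family that is found inside cells and can be released from them. The series concerns how the antibody affects growth of the lines, and the comparisons below ask which transcripts differed in level with it. Each of the 4 groups was 1 array, with no replicates, so a difference within a line has no replicate check and no test. The number of arrays limits the precision. The 75th percentile of the processed signal over non-control spots was 321 in untreated H2052, 561 in antibody-treated H2052, 504 in untreated H2452 and 391 in antibody-treated H2452. In the same order, 13973, 14187, 13853 and 13983 genes were well above background, and no spot was saturated. Levels are log2 signals relative to the array's 75th percentile over probes well above background on all 4 arrays. Between repeated spots of 1 probe, the SD of a log2 fold change was 0.088 in H2052 and 0.083 in H2452, which covers spot noise and leaves out culture, RNA and labelling error.

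S100A11 itself, the target of the antibody, was at 2.22 in untreated and 2.24 in antibody-treated H2052, and at 3.02 and 2.90 in H2452. Its log2 fold change was 0.01 in H2052 and -0.12 in H2452, and its other probe gave 0.04 and -0.09.

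Spots that stood above the same spots on the other arrays lay together in rounded patches and streaks. Such bright patches held 5.15% of the spots in untreated H2052, 3.0% in antibody-treated H2052, 4.0% in untreated H2452 and 2.95% in antibody-treated H2452. Over all arrays, 14.1% of the spots lay in a patch on at least 1 array, against 1.38% once spots were shuffled over the array. Of the spots that differed at least 2-fold between the 2 arrays of H2052, 77.4% lay in a patch, against 8.08% of all spots well above background on both. In H2452 these shares were 35.6% and 6.99%. Genes are therefore named below from values with patch spots left out on all arrays, a setting chosen after the data were seen, and counts are given both ways. Gene list values keep all spots.

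**Figure D1:**
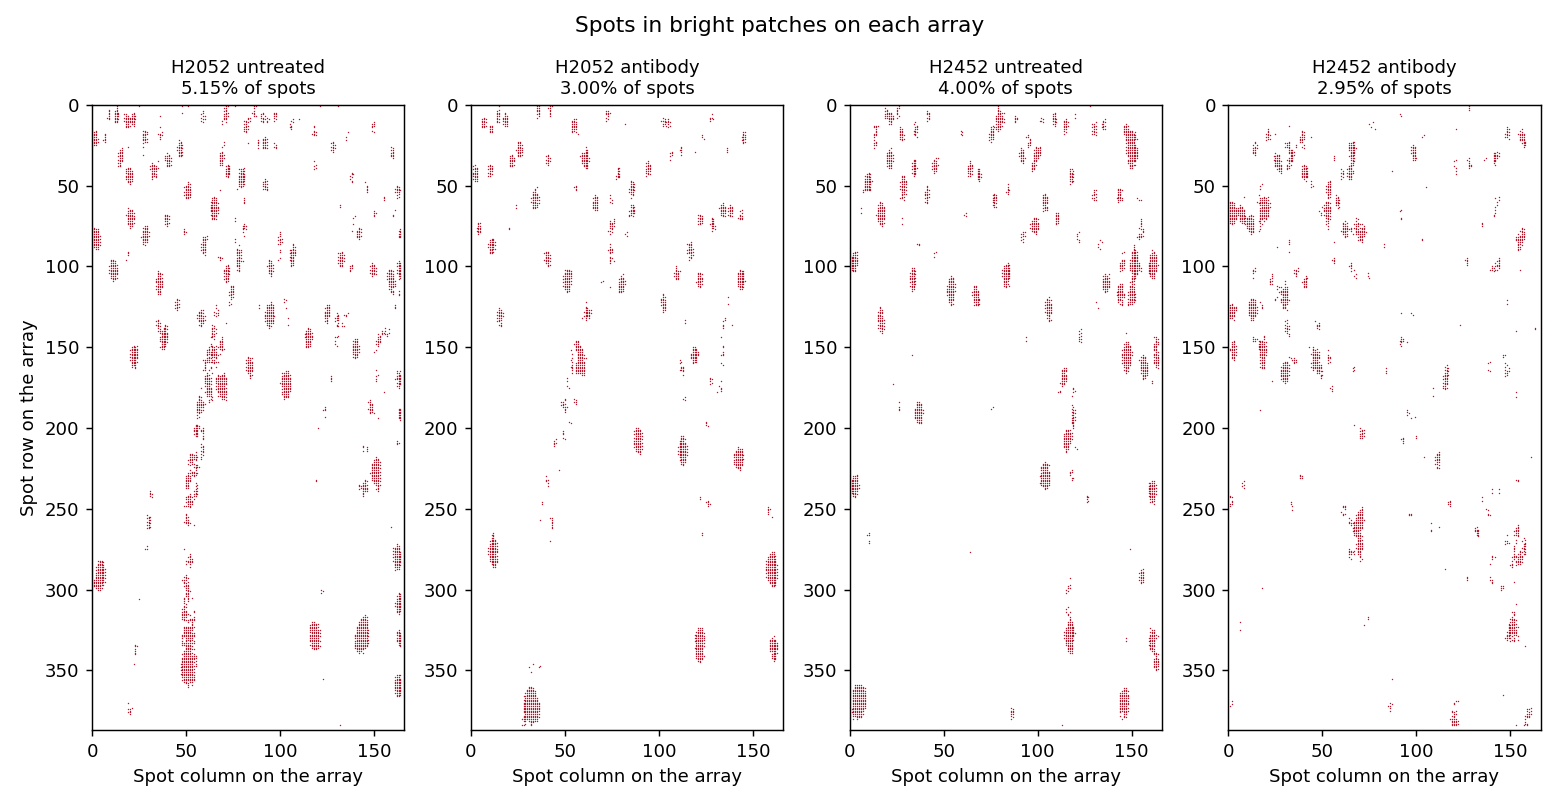
Position of the spots in bright patches on each of the 4 arrays, by spot column (horizontal axis) and spot row (vertical axis); each point is 1 spot. Patches held 5.15%, 3.0%, 4.0% and 2.95% of the spots.

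In H2052 the transcripts that were lower with the antibody included those of MMP1, a collagenase gene, and CT45A1, a cancer-testis gene. MMP1, averaged over 10 spots, was at 5.03 in untreated and 3.64 in antibody-treated cells, a log2 fold change of -1.39. CT45A1 had the largest difference, -2.41, and CTAG1A, also a cancer-testis gene, was at -1.04. The other named genes on this side were the costimulatory ligand gene CD86 at -1.16, NCCRP1 at -1.15, the histone gene H2AC6 at -1.14, OR1J1 at -1.07, CASC15 at -1.04, IGFL3 at -1.02 and SCUBE1 at -1.01. For H2AC6 this was a dimmer probe, since the brighter one, at -0.42, lay in a patch. On the higher side, 3 of the 10 named genes code for small RNAs that guide RNA modification: SCARNA14 at 1.36, SNORA1 at 1.33 and SNORA28 at 1.15. CCDC159 was at 1.20 and TMEM63A, a membrane channel gene, at 1.06. The remaining named genes, SH3RF3, DPF3, NIPSNAP3B, SEC61A2 and ST7, were at 0.96, 0.96, 0.95, 0.94 and 0.93.

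With all spots, 43 genes were at least 2-fold higher and 63 at least 2-fold lower with the antibody in H2052, of 13662 well above background on both arrays. With patch spots left out, 5 were higher and 10 lower of 12238. Scaling on spike-in control probes turned the balance with all spots, to 149 higher and 37 lower. Of the 106 genes in the first count, 89 had their spot in a patch, among them ZNF204P at 4.08 and GNG12-AS1 at -3.52. Some genes were well above background on only 1 of the 2 arrays, where the fold is a bound. ABCC8, a subunit of potassium channels, was at least 10.6-fold lower, OR5K2 at least 8.64-fold lower and SLC16A8 at least 6.29-fold lower. ZDHHC15 was at least 10.8-fold higher, OR2D2 at least 6.60-fold higher and MESTIT1 at least 5.25-fold higher. Each bound rests on 1 spot. None of the 8 genes of the first count that had another measurable probe was at least 1.5-fold different in the same direction on that probe. With patch spots left out, none of the 15 genes had another measurable probe.

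In H2452 the transcripts that were higher with the antibody included those of FMOD, a matrix gene, and SAA1, an acute phase gene. FMOD, which codes for the collagen-binding proteoglycan fibromodulin, was 7.33-fold higher over 10 spots (log2 fold change 2.87), and ELN, which codes for elastin, was at 1.91. SAA1 was at 2.51, its relative SAA2 was at least 4.61-fold higher, and the complement gene CFB was at 1.79. NTRK2, a neurotrophin receptor gene, was at 1.72, and PTGIS, which codes for prostacyclin synthase, at 1.74. Further genes on this side were CIMAP1D at 1.87, IGFL2 at 1.83, ZNF699 at 1.74 and KRTAP3-3 at 1.90. KRTAP3-3 was at -0.04 under a stricter definition of patches. SNORD24, a small nucleolar RNA, was at least 10.6-fold higher and KRTAP16-1 at least 4.92-fold higher.

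On the lower side in H2452, the cytokine gene IL24 was at -1.89 and CD274, which codes for the immune checkpoint ligand PD-L1, at -1.58. PCNA-AS1, antisense to the replication clamp gene PCNA, had the largest difference, -2.74. BLZF1 was at -1.61, DOCK4 at -1.44, TINAGL1 at -1.42, PIAS1 at -1.39 and the mitochondrial carrier gene UCP3 at -1.36. RAD1, a checkpoint gene, was at -1.82 on its brightest probe and at -0.05 on the other. VNN1, which codes for the pantetheinase vanin-1, was at least 14.8-fold lower, TCF23 at least 5.12-fold lower and ZP2 at least 3.77-fold lower. With all spots, 103 genes were at least 2-fold higher and 67 at least 2-fold lower of 13548. With patch spots left out, 87 were higher and 28 lower of 12151. Cyclic loess turned the balance with all spots, to 66 higher and 86 lower. In the first count, 48 of 170 genes had their spot in a patch, and 3 of the 15 with another measurable probe were at least 1.5-fold different in the same direction on it. With patch spots left out, 11 of the 115 genes had another measurable probe, and 3 of these 11 were so.

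Genes that were higher in both lines included IGFBP3, which codes for a binding protein of insulin-like growth factors, and a group of small RNA genes. Over 10 spots, IGFBP3 was at 0.74 in H2052 and 1.19 in H2452. Of the genes named on this side, 6 code for small nucleolar or Cajal body RNAs. SNORA28 was at 1.15 and 1.33, SNORA1 at 1.33 and 1.14, SNORA23 at 0.86 and 1.03, SCARNA11 at 0.85 and 1.38, SCARNA18 at 0.75 and 0.91, and SNORA27 at 0.71 and 0.80. SH3RF3, OLFML3, MIR9-2HG and TENM4 were at 0.96, 0.84, 0.73 and 0.72 in H2052 and at 1.07, 0.76, 0.90 and 0.79 in H2452.

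Genes that were lower in both lines were led by IL24, at -0.83 in H2052 and -1.89 in H2452, and by the sortilin family gene SORCS3, at -0.82 and -0.9995. CTAG1A was at -1.04 and -0.78. The myeloid genes TYROBP, C3AR1 and MEFV were at -0.83, -0.59 and -0.77 in H2052 and at -0.58, -0.65 and -0.61 in H2452. The remaining named genes, DICER1-AS1, DSCR9, RNF222, POFUT1, PLCB1 and OLMALINC, lay between -0.80 and -0.54 in both lines. POFUT1 was at 0.12 and 0.33 on its other probe.

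With all spots, 3 genes were at least 2-fold higher in both lines and 1 was at least 2-fold lower, where independent lists would share 0.203 and 0.173. The higher ones were SNORA28, SNORA1 and the olfactory receptor gene OR7G1, at 1.22 and 3.25, whose spot lay in a patch. The lower one was PRRX1, a homeobox gene, at -1.66 and -1.51, in a patch on both untreated arrays. With patch spots left out, SNORA28 and SNORA1 were the 2 left, and none was lower. Across the 13229 genes well above background on all arrays, the log2 fold changes of the lines had a Pearson r of 0.220 and a Spearman rho of 0.261. Genes are not independent replicates, so no p is given. Of these genes, 60.8% had the same sign in both lines. With normexp background correction r was -0.0151.

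The antibody effect over both lines was tested with limma, with the line as a block and the disagreement between the lines as the error. Of 14159 genes, 5 passed at an adjusted p under 0.05, all lower with the antibody, and 0 were higher. They were CPA1, a pancreatic carboxypeptidase gene, CFAP46, a cilia gene, GALR1, a galanin receptor gene, MAGEA2B, a cancer-testis gene, and LOC153910, named here after its values were seen. CPA1 was at least 28.1-fold lower in H2052 and at least 21.3-fold lower in H2452 (limma adjusted p = 0.0194). All 5 were well above background on the untreated arrays only, and all 5 spots lay in a patch on both untreated arrays, as 0.259% of spots did. With patch spots left out, 0 of 12649 genes passed, the smallest adjusted p was 0.595, and 1009 genes had an unadjusted p under 0.05 where 632 would by chance. With all spots the unadjusted count was 1073, where 708 would by chance. Over the same 14159 genes it was 299 with normexp and 2237 with the authors' values. Genes can vary together between single cultures, so these excesses are a description and no test of the antibody. The calls depended on the settings. An intensity trend gave 18 higher and 17 lower, and spike-in scaling, with infinite prior degrees of freedom, 138 higher and 53 lower. In simulated data of the same design, limma recovered 0 of 50 genes with a log2 change of 1 and 42 of 50 with a change of 2.

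Among the gene lists fixed beforehand, those of the extracellular matrix and of cholesterol synthesis stood apart in the same direction in both lines, relative to matched random lists. The median of 19 matrix genes was 0.25 in H2052 and 0.47 in H2452, at the 100th percentile of 10000 random lists matched on expression in each, and 15 of the 19 were higher in both. The collagen genes COL4A1, COL1A2 and COL1A1 were at 0.51, 0.47 and 0.27 in H2052 and at 0.85, 0.88 and 0.90 in H2452, and TNC, the tenascin C gene, was at 0.36 and 0.82. The median of 22 cholesterol synthesis genes was -0.19 and -0.20, at percentiles 0 and 0.1, with 16 of the 22 lower in both, and scaling on spike-in control probes, which put the median of all genes at 0.35 in H2052, gave 0.17 there, at percentile 0. DHCR7, which codes for a reductase of the last steps, was at -0.35 and -0.53 and SQLE, the squalene epoxidase gene, at -0.39 and -0.39. INSIG1 was at -0.84 and -1.26, with its spot in a patch on untreated H2452. No member of either list passed limma over all genes or adjusted over the list alone. In H2452 the cholesterol median came inside the central 95% with normexp (-0.10, percentile 7.63) and with the stricter patches (-0.05, percentile 37.8).

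**Figure D2:**
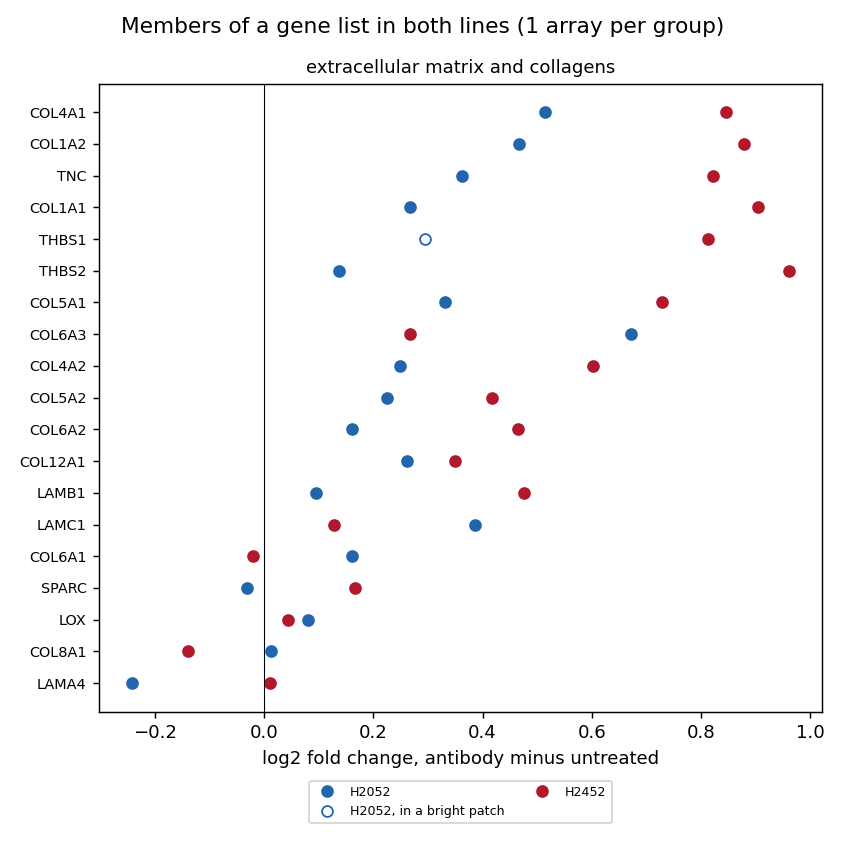
Log2 fold change with the antibody (horizontal axis) of each measured member of the extracellular matrix list, in H2052 (blue) and H2452 (red), with 1 array per group and no error bars. Open circles have their spot in a bright patch on an array of that line; 15 of the 19 genes were higher in both lines.

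Targets of transforming growth factor beta and genes of epithelial-mesenchymal transition had a median of 0.13 in H2052, at percentile 99.9, though with normexp it was -0.04 (percentile 89.2), and with the authors' values it was at percentile 93.7. In H2452 the median was 0.13, inside the central 95% at percentile 96.0, and it came outside with patch spots left out (0.21, percentile 99.1), with the mean over probes (0.17, percentile 98.7) and with no background filter (0.15, percentile 98.3). Of the 22 members, 10 were higher in both lines, among them TGFBI at 0.28 and 0.88, the inhibitory gene SMAD7 at 0.31 and 0.62 and FN1, the fibronectin gene, at 0.13 and 0.72. For the antibody effect limma called 0 members of this list over all genes, and 1 adjusted over the list alone. Mesothelial and mesothelioma markers had medians of 0.06 in H2052 (percentile 98.0; -0.09 with normexp, percentile 67.8) and 0.18 in H2452 (percentile 98.8), with MSLN, the mesothelin gene, at 0.22 and 0.56 and WT1 at 0.50 and 0.15. Both mesothelial medians came inside the central 95% with patch spots left out, at percentiles 95.3 and 97.0.

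Another set of lists lay on opposite sides of matched random lists in the 2 lines. Genes of G2/M and mitosis had a median of 0.09 in H2052 (percentile 100) and -0.21 in H2452 (percentile 0.03), with 18 of 24 members higher in H2052 and 20 lower in H2452. The cyclin genes CCNA2 and CCNB2 were at 0.17 and -0.10 in H2052 and at -0.82 and -0.38 in H2452. TOP2A, the topoisomerase gene, was at 0.66 and 0.37. The NF-kB and inflammatory cytokine list had medians of -0.22 (percentile 0; 0.15 with spike-in scaling, at the same percentile) and 0.22 (percentile 99.5), and the H2452 median came inside with cyclic loess (0.14, percentile 97.4). Of its 14 members, 12 were lower in H2052 and 10 higher in H2452, among them the chemokine gene CCL2 at -0.23 and 0.56 and BIRC3, an inhibitor of apoptosis, at -0.20 and 0.70. The NRF2 and oxidative stress list had medians of -0.22 (percentile 0.04; 0.14 with spike-in scaling, at the same percentile) and 0.16 (percentile 98.4). The H2052 median came inside with normexp (-0.19, percentile 14.6), and the H2452 median with patch spots left out (percentile 97.3). Of its 17 members, 13 were lower in H2052 and 13 higher in H2452, but the quinone reductase gene NQO1 and AKR1C3 were higher in both, at 0.37 and 0.09 in H2052 and at 0.85 and 0.92 in H2452. Cytosolic ribosomal protein genes had medians of -0.37 (percentile 0) and 0.14 (percentile 99.9), but with quantile normalization the H2452 median was -0.09 and both came inside the central 95%, at percentiles 36.5 and 38.0. All 26 members were lower in H2052 (median -0.0033 with spike-in scaling), with RPS24 at -0.38 and RPS9 at -0.27, and 23 were higher in H2452, where these genes were at -0.08 and -0.06. None of the members of these lists passed limma over all genes or adjusted over the list alone.

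Some lists stood apart in 1 line. In H2052 the median of 19 replication-dependent histone genes was -0.39 (percentile 0), and all 19 were lower (median -0.03 with spike-in scaling), with H4C15 at -0.53 and H3C10 at -0.48. In H2452 it was -0.07 (percentile 27.3). Kruppel-like factors had a median of -0.15 in H2052 (percentile 0.39; 0.21 with spike-in scaling, at the same percentile) and -0.0042 in H2452, with KLF13 at -0.16 and -0.32. Epidermal growth factor family genes, mesothelioma tumour suppressor genes and housekeeping genes lay above matched random lists in H2052, with medians of 0.18, 0.20 and -0.04 (percentiles 98.4, 98.6 and 97.9), and inside in H2452, at 0.15, 0.13 and -0.02; the housekeeping median in H2052 was 0.05 with quantile normalization, 0.02 with cyclic loess and 0.32 with spike-in scaling. The epidermal growth factor and housekeeping medians came inside in H2052 with patch spots left out, at percentiles 74.9 and 96.7. The former was also inside with normexp (0.0052, percentile 70.4) and the mean over probes (0.0061, percentile 49.1), and the tumour suppressor median with normexp (percentile 96.95), the mean over probes (percentile 96.95), the authors' values (percentile 94.98) and no background filter (percentile 96.1). In H2452 the matrix proteases and their inhibitors had a median of 0.33 (percentile 99.97; -0.05 in H2052, percentile 45.5), with the aggrecanase gene ADAMTS5 at 1.29 and TIMP3, which inhibits such proteases, at 0.59. Immediate early genes had a median of -0.22 in H2452 (percentile 0.8; -0.10 in H2052), with NR4A3 at -0.57 and ATF3 at -0.32. The Kruppel-like and immediate early medians came inside with the authors' values (percentiles 7.96 and 3.5) and with no background filter (percentiles 6.38 and 7.3). That these lists differ between the lines was not tested.

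**Figure D3:**
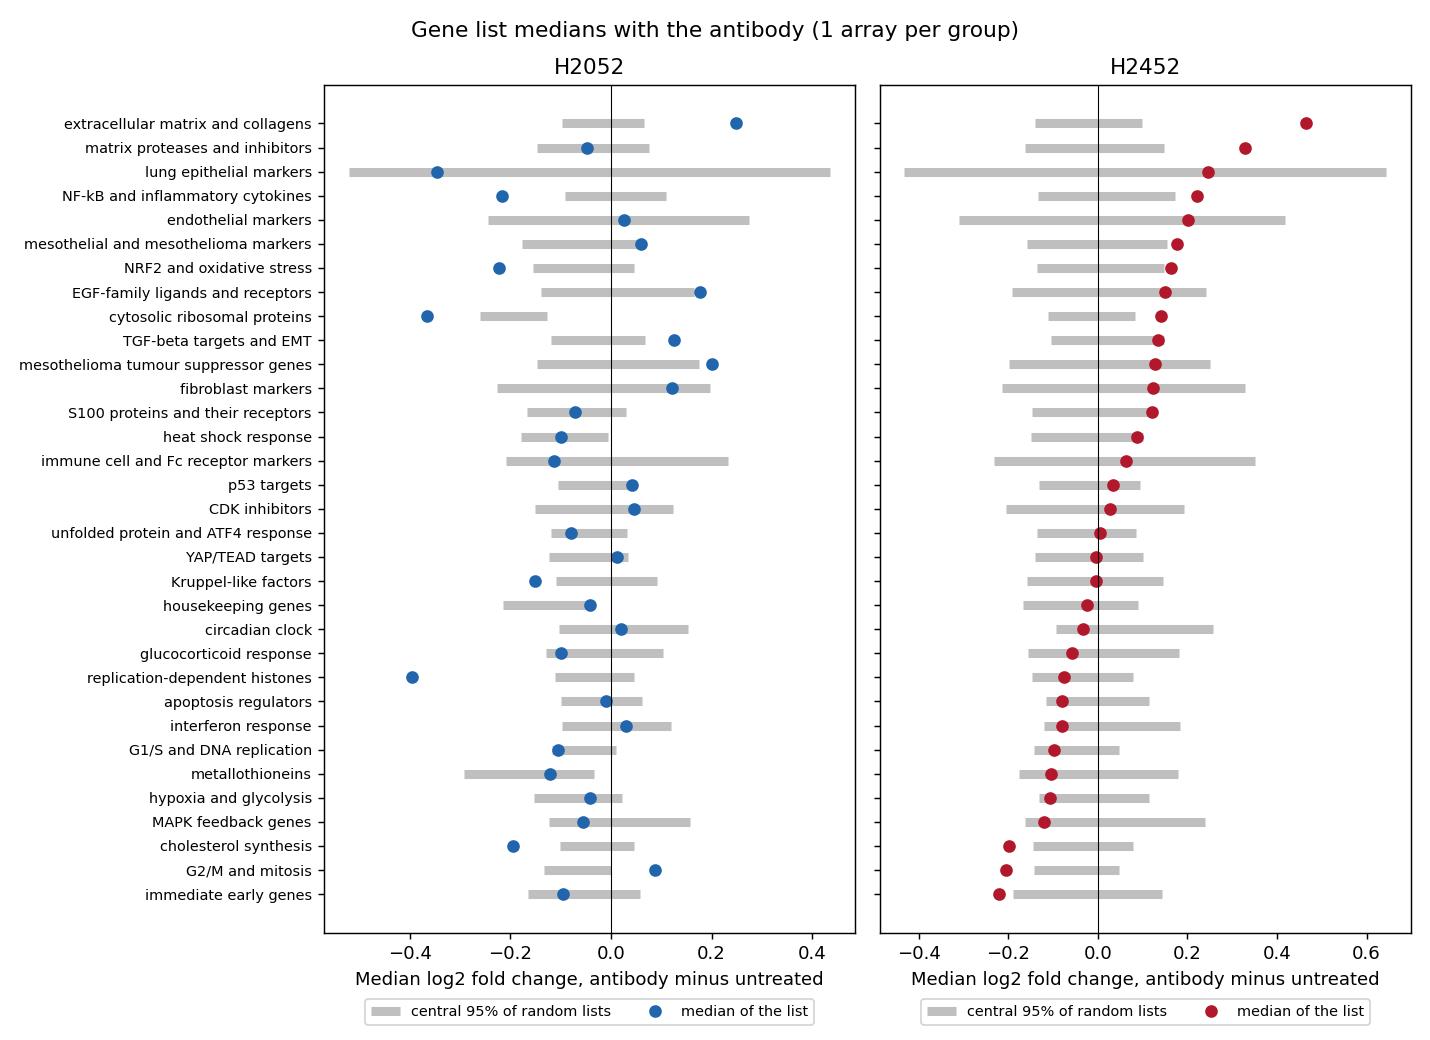
Median log2 fold change with the antibody (horizontal axis) of each gene list in H2052 (left) and H2452 (right), with 1 array per group; grey bars hold the central 95% of 10000 random lists of the same size matched on expression. The extracellular matrix list, at 0.25 and 0.47, and the cholesterol synthesis list, at -0.19 and -0.20 (0.17 in H2052 with spike-in scaling), lie outside the bars on the same side in both lines.

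The remaining 18 of the 33 lists lay inside the central 95% in both lines. S100 proteins and their receptors had medians of -0.07 in H2052 and 0.12 in H2452, but with quantile normalization these were 0.05 and -0.03, with patch spots left out the H2452 median was -0.07, and with normexp the H2052 median was outside (-0.0056, percentile 97.7). Medians were -0.05 and -0.12 for feedback genes of the MAPK pathway, with DUSP6 at -0.32 and -0.92 and ETV5 at -0.30 and -0.69. Genes of G1/S and DNA replication were at -0.10 and -0.10, p53 targets at 0.04 and 0.03, apoptosis regulators at -0.01 and -0.08 and inhibitors of cyclin-dependent kinases at 0.05 and 0.03. Of the last, CDKN2A was at 0.26 and 1.67. Medians were 0.03 and -0.08 for the interferon response, 0.01 and -0.0033 for YAP/TEAD targets, -0.08 and 0.01 for the unfolded protein and ATF4 response, and -0.10 and 0.09 for the heat shock response. Hypoxia and glycolysis genes were at -0.04 and -0.11, with ANGPTL4 at -0.16 and 1.06. Metallothioneins were at -0.12 and -0.11, glucocorticoid response genes at -0.10 and -0.06 and circadian clock genes at 0.02 and -0.03. Of markers of other cell types, 4 immune and Fc receptor markers had medians of -0.11 and 0.06, 5 fibroblast markers 0.12 and 0.12, 3 endothelial markers 0.03 and 0.20, and 3 lung epithelial markers -0.34 and 0.25. Of these 18 lists, some came outside in 1 line under an alternative, among them metallothioneins (-0.38, percentile 0.02) and the interferon response (-0.16, percentile 0.78) in H2452 with the stricter patches and YAP/TEAD targets in H2052 with quantile normalization (0.08, percentile 97.7). In all, 22 of 66 medians lay outside, where 3.3 would if the genes of a list varied independently. Genes of a list can vary together between single cultures, so the excess is a description and no test of the antibody.

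The lines themselves differed in far more genes. By limma, with the antibody as a block, 1540 genes were higher and 1247 lower in H2452 at an adjusted p under 0.05, and 1150 of these differed at least 2-fold. The error here is how far the line difference varied with treatment, over 2 arrays of each line that are not replicate cultures. NLGN4X, which codes for the synaptic adhesion protein neuroligin 4, was 8.65 ± 0.15 (SE) higher in H2452 on the log2 scale (limma adjusted p = 0.00365 with patch spots left out), ADGRG7 7.70 ± 0.15, CACNG7 6.69 ± 0.33 and RPL39L 6.57 ± 0.13. These 4, with ZNF502, KLF8, SAA1 and PAX1, were not well above background on either array of H2052, and MEIOB and VPS9D1-AS1 on neither of H2452, so their fitted values depend on signal near background. CEMIP, a hyaluronan-binding gene, was 5.88 ± 0.18 higher, and ZNF502, KLF8, SAA1 and PAX1 were between 5.11 and 5.97 higher. Lower in H2452 were MEIOB, a meiosis gene, at -7.23 ± 0.28, CYBA, a subunit of the NADPH oxidase, at -5.71 ± 0.37, VPS9D1-AS1 at -5.16 ± 0.11, IL1RAPL1 at -5.08 ± 0.69, SNX32 at -4.98 ± 0.15 and MANCR at -4.51 ± 0.24. Another 5 genes that the naming rule gives, DOK5, TPSAB1, NEB, GTSF1 and PLCXD3, had their spot in a patch. S100A11 was 0.73 ± 0.11 higher in H2452 (limma adjusted p = 0.0295).

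Of the gene lists, NF-kB and inflammatory cytokine genes had the highest median line difference, 1.01 (percentile 100), and limma called 8 of 16 higher in H2452 and 1 lower. Matrix genes had a median of 0.40, TGF-beta and EMT genes 0.42 and interferon response genes 0.48, at percentiles 100, 99.99 and 99.99. Limma called 7 of 21, 10 of 22 and 8 of 18 of them higher. MAPK feedback genes were lower in H2452, with a median of -0.81 (percentile 0) and 7 of 10 called lower. Adjusted over the list alone, 9 members of the NF-kB list, 12 of the matrix list, 14 of the TGF-beta list, 13 of the interferon list and 8 of the MAPK list passed. Cholesterol synthesis genes had a median of -0.34 (percentile 0.07). With normexp background correction 336 genes were higher and 175 lower, and with the authors' values rounded to 1 decimal limma called 0.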

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

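Of the tests in this part, the one for a brightness trend was chosen before its result was seen, and those for bright patches, for the ribosomal list alone and for the called genes only after.

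In H2052 and H2452, 4 gene lists lay on opposite sides of matched random lists. The H2452 median minus the H2052 median was -0.29 for G2/M and mitosis, 0.44 for NF-kB and inflammatory cytokines, 0.39 for NRF2 and oxidative stress and 0.51 for cytosolic ribosomal proteins. These were marked because the medians of each list lay outside on opposite sides and had opposite signs in the lines. The difference itself was not tested.

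The antibody array was the brighter of the pair in H2052 and the dimmer in H2452, so a signal trend could move lists in opposite directions. With cyclic loess, which removes such a trend, 7 of the 8 medians stayed outside on the same side, all but NF-kB in H2452. The random lists are matched on mean expression, so a smooth trend moves them too, before and after loess. Before loess, for the ribosomal list in H2052, their median was -0.19. The count is therefore a weak test of such a trend, and no conclusion is drawn from it. With patch spots left out 7 of 8 also stayed, all but NRF2 in H2452, which argues against bright patches. For the ribosomal list, 2 of 4 medians stayed outside over quantile normalization and cyclic loess, both of them with loess, so a trend at the bright end and a change in these transcripts cannot be told apart while the corrections disagree. A response that differs between the lines stays open for the other 3 lists, with 1 culture per group.

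The 5 genes that limma called lower with the antibody over both lines, CPA1, CFAP46, GALR1, MAGEA2B and LOC153910, were weighed next. All 5 called genes had their spot in bright patches on the untreated arrays, on both of them, and no call was left once patch spots were left out, so bright patches are a likely source. These probes themselves are absent from that fit, so it gives no value for them. A loss of the transcripts cannot be told apart from no expression by their other probes, of which 0 of 4 were well above background on both untreated arrays, as a few weak probes decide nothing.

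The control probe ERCC-00142, outside the main measurement, had a median signal of 80.0 on the antibody array of H2452, with 35 of 35 spots well above background. It was marked because most of its spots were well above background on that array alone. The negative-control spots on that array had a 95th percentile of 4.63. On the other arrays, untreated H2052, antibody-treated H2052 and untreated H2452, the ERCC-00142 median was 3.38, 4.88 and 5.95. The control probe ERCC-00148 had 35 of 35 spots well above background on every array, so it was not marked. Its medians were 51.2 and 65.2 in untreated and antibody-treated H2052, and 74.9 and 52.7 in untreated and antibody-treated H2452.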

How the results depend on the processing

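The 2 patch alternatives and the percentile over all probes were chosen after seeing the data; the others were chosen before the data were examined. Where no reason is given, the cause was not tested.

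Normexp gave 14 genes higher and 33 lower in H2052, 36 higher and 16 lower in H2452, 1 higher and 0 lower in both lines, and a correlation of -0.0151 between lines. With normexp limma called 0 genes lower with the antibody (299 at an unadjusted p under 0.05), and 336 higher and 175 lower in H2452 than in H2052. Cyclic loess gave 66 genes higher in H2452 and 2 lower in both lines. Limma called 8 genes lower with the antibody with the percentile over all probes, 8 with quantile normalization and 8 with cyclic loess. Spike-in scaling put the median of all genes at 0.35 in H2052 and 0.01 in H2452, gave 149 genes higher and 37 lower in H2052 and 12 higher in both lines, and limma then called 138 higher and 53 lower with the antibody and 1005 higher in H2452. The change in the H2052 counts follows from that shift. With spike-in scaling limma's prior degrees of freedom were infinite, against 2.85 in the main fit, so its calls there are to be read with care. The authors' values gave 2 genes lower in both lines, and limma called 0 lower with the antibody (2237 at an unadjusted p under 0.05) and 0 higher and 0 lower between lines (5442 at an unadjusted p under 0.05). The mean over probes gave 4 genes lower in both lines and 0 limma calls lower with the antibody (1015 at an unadjusted p under 0.05).

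With bright patches left out, 5 genes were higher and 10 lower in H2052, 28 lower in H2452 and 0 lower in both lines, and limma called 0 lower with the antibody (1009 at an unadjusted p under 0.05). The stricter patches gave 5, 8, 28 and 0, and 0 limma calls lower (1025 at an unadjusted p under 0.05). The fall in H2052 follows from the patches, which held 77.4% of the spots that differed at least 2-fold. Line difference counts were 1492 higher and 1254 lower with patches left out, and 2472 of the 2787 genes called remained. Limma called 0 genes lower with the antibody among those well above background on all 4 arrays (1337 at an unadjusted p under 0.05), a filter that leaves out the 5 called genes.

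With no background filter, 525 genes were higher and 878 lower in H2052, 740 higher and 558 lower in H2452, 67 higher and 79 lower in both lines, and the correlation was 0.0535. Limma then called 0 lower with the antibody (834 at an unadjusted p under 0.05) and 0 higher and 0 lower between lines (4522 at an unadjusted p under 0.05). At 1.5-fold, 184 were higher and 207 lower in H2052, 584 and 271 in H2452, and 39 and 17 in both. At 3-fold these were 19 and 29, 21 and 15, and 0 and 0, which follows from the thresholds. An intensity trend gave 18 genes higher and 17 lower with the antibody, and 2658 higher and 2732 lower between lines. With no replicate block, the line left out of the fit, limma called 0 lower with the antibody (131 at an unadjusted p under 0.05), as the line difference then enters the error. A robust prior called 4 lower.

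Gene lists above matched random lists in H2052 numbered 7, and 3 with normexp, 4 with cyclic loess, 3 with the authors' values, 4 with the mean over probes, 4 with bright patches left out and 3 with no background filter. Of the 22 list medians outside, between 14 (normexp and the authors' values) and 19 (mean over probes and stricter patches) stayed outside on the same side. The number that crossed to the other side was 0. With the percentile over all probes, median centring and spike-in scaling all 22 stayed, which tests nothing. These 3 move a list and its random lists alike.

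Among named genes at least 2-fold different with all spots, log2 fold changes changed sign in 16 cases. Sign changes of smaller differences were not counted apart. With bright patches left out and with the stricter patches, BRPF3 was at 0.71 and 0.71 in H2052, ZNF589 at 0.40 and 0.41, HERC6 at 0.48 and 0.48, NEB at -0.23 and -0.23, ATP13A4 at -0.83 and -0.83, CLEC12B at 0.59 and 0.60, and CACNA2D3 in H2452 at 0.25 and 0.24. OR7G1 was at -0.15 in H2052 with normexp, and KRTAP3-3 at -0.037 in H2452 with the stricter patches. Of the other values for named genes, sign changes of smaller differences among them, 3283 stayed within their limits and 930 moved beyond them.

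Each line on its own left no residual degree of freedom, so that alternative gave values for the named genes and no counts. The filter for all 4 arrays gave no separate list medians, which use it already. Between 46.9% and 48.9% of the probes were well above background on an array, and this signal over background limits which genes can be compared. Of 50 simulated genes, limma recovered 0 at a log2 change of 1, so smaller changes with the antibody are not detectable by it here.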

Other observations

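Of the tests in this part, the one for scaling between arrays was chosen before its result was seen and narrowed to 2 settings after, and those for the yield of short RNAs were chosen only after, as was the class of genes itself.

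SNORA and SCARNA genes code for box H/ACA and Cajal body RNAs, which guide modification of ribosomal and spliceosomal RNA. Of 100 measured, 85 were higher with the antibody in H2052 and 97 in H2452, with medians of 0.27 and 0.55, both at the 100th percentile of matched random lists. The class was chosen after 6 of its genes were seen higher in both lines. SNORD genes, which code for box C/D RNAs, had medians of 0.03 in H2052 (58 of 110 higher, percentile 78.5) and 0.35 in H2452 (95 of 110 higher, percentile 100). With normexp the H2052 SNORD median was -0.20, where that of all genes was -0.09. The SNHG host genes had medians of -0.10 and -0.0068 over 18 genes, the first at 0.27 with spike-in scaling, the latter at 0.0062 with normexp, 0.0060 with spike-in scaling and 0.04 with patch spots left out. With patch spots left out, the medians of 88 SNORA and SCARNA genes were 0.27 and 0.56, and with normexp the H2052 median of the class was 0.09.

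Scaling between arrays is argued against as the whole cause, since over quantile normalization and cyclic loess the lowest class median relative to all genes was 0.26. A single factor per array moves the class and all genes alike, so the other scalings test nothing here. A higher yield of all short RNAs in the treated sample stays open in H2452, and in H2052 the settings disagree. The SNORD median was 0.0333 in H2052 and 0.35 in H2452, below the class medians by less than the SD of the SNORD genes, 0.26 and 0.33. That SD is the spread of single genes, not the error of their median. By this measure alone, such a yield and a change in the class alone cannot be told apart in the main setting. With patch spots left out, the H2052 SNORD median was 0.02 against a class median of 0.27, a gap above the SNORD SD of 0.22. The H2052 gap also exceeded that SD with the stricter patches, normexp and the authors' values, which goes against such a yield there. A change in these RNAs with the antibody stays open as well, with 1 culture per group.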
